A study of Mus musculus with 12 samples.

How the data were processed

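RNA of 12 skin samples from newborn mice was labelled with Cy3 and hybridised to 1-colour Agilent mouse miRNA arrays, per the labels. The authors' deposited scanner output was made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. Per the file headers, each of the 47604 spots has a processed intensity (linear, background-subtracted and spatially detrended, not normalized between arrays), a median pixel intensity, a local background intensity and flags for spots well above background, saturated or outlying. Per the file headers the grid names mouse build mm9. The series' deposited value table holds intensity too: in 0 of 12948 cells did it differ by more than a tolerance of 1e-06 from the same array's total gene signal in the scanner files (largest absolute difference 0), so its scale is linear with no centring, and its median was 0.1 on every array, the value given to undetected miRNAs.

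Groups were taken from the genotype labels: K5Cre(wt), caNrf2, wt and dnNrf2, with 3 arrays each. The file headers place the arrays on 2 slides: slide 1 held all wt and dnNrf2 arrays with K5Cre(wt) replicate 1 and caNrf2 replicate 1 (8 arrays), and slide 2 held the other 4. The main settings, the lists, the tests and the alternatives were chosen before the data were examined, except those named here as added.

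Mouse spots numbered 43160 per array (1079 miRNAs, 2754 probes), beside 2164 control spots and probes for 57 viral miRNAs. Control spots and spots with an outlier flag (3.68%) were left out; no spot was saturated. The processed signals of a probe's spots (10 to 40 per probe) were averaged, and the probe means of a miRNA (1 to 4 probes) were summed. Each array was divided by its 75th percentile over the 334 miRNAs detected on all arrays. Scaled values were then floored at 0.00483, the median over arrays of the lowest scaled signal of a detected miRNA, and put on the log2 scale; 0.947% of tested values lay at the floor. Detection was Agilent's call per miRNA. A miRNA was tested if it was detected on all 3 arrays of at least 1 group, which left 387.

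All 4 groups were fitted together in limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8) with 1 mean per group, lmFit and eBayes without trend (8 residual and 2.16 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the 387 miRNAs and a threshold of 0.05. Contrasts were caNrf2 minus K5Cre(wt), dnNrf2 minus wt, the difference of these differences, and wt minus K5Cre(wt). Where most spots of every probe of a miRNA failed to lie well above background on every array of a group, the fold is a bound: the other group's mean over the higher, per array, of the dim group's own value and the lowest value of a miRNA well above background. Means of normalized log2 values were used for these bounds.

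Lists were tested with camera (preset correlation 0.01) where at least 3 members were tested, adjusted over 17 lists, with camera at an estimated correlation and fry beside it; fry asks whether a list's members move one way on balance and does not compare them with other miRNAs. No list call in either comparison of a transgene with its control held with the estimated correlation. By fry, the miR-29 list (adjusted p = 0.00955) and the melanocyte and nerve list (0.0256) passed in caNrf2, and none in dnNrf2. In the melanocyte and nerve list the log2 change was 1.23 for miR-138, which was near background. It was 0.038 for miR-128, 0.037 for miR-219-5p, 0.041 for miR-211* and -0.217 for miR-211, so the members did not move together. The 18 lists were: miR-29 family; miR-200 family; keratinocyte and epidermal; proliferation and wound or inflammation response; dermal mesenchyme and smooth muscle; skeletal muscle; leukocyte; erythroid; endothelial; melanocyte and nerve; let-7; miR-17-92 and paralogues; miR-30; miR-15 and miR-16; miR-99 and miR-125; miR-23, miR-24 and miR-27; miRNAs reported to target Nrf2 or Keap1 mRNA or to depend on Nrf2; and the imprinted Dlk1-Dio3 locus. An entry took every arm on the array.

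The rule for named miRNAs was, per comparison, up to 10 with the largest rise and up to 10 with the largest fall among those past the threshold; where fewer than 10 passed, those with the smallest p were added up to 10. It also took every tested member of the miR-29 and miR-200 families, a fixed set of tissue miRNAs (among them miR-203, miR-205, miR-31 and miR-126), up to 4 members of each list with the smallest p, and up to 5 by smallest p for the interaction and the control groups. The other called miRNAs of the control groups (miR-148a*, miR-15b, miR-425, miR-335-5p and miR-200a) are named beyond that rule, chosen after their values were seen.

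The fit was tested on simulated data with 387 miRNAs, the arrays' own spread and 30 miRNAs changed per size, in 20 runs. In the caNrf2 comparison 61.8% of log2 changes of 0.5 and 86% of those of 1 were recovered, with 4.21% of calls false; in the dnNrf2 comparison 63% and 89.5%, with 4.79% false. A shifted list was found in 20 of 20 runs in each. The simulated noise was drawn separately for each miRNA, whereas 50.3% of the arrays' within-group variance lay in 1 component. These rates therefore do not cover variation shared between miRNAs, for single miRNAs or for lists. More miRNAs were changed in the simulation than were called in the data, which eases the adjustment, so recovery in the data may be lower.

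Alternatives fixed before the data were examined were: scaling over all miRNAs, quantile normalization, scaling to the median, normexp background (offset 50), Agilent's total gene signal, mean log2 probe values, the median over spots, no filter, only miRNAs detected on all arrays, the floor at 0.5 and 2 times its value, eBayes with trend, array weights, only the 6 arrays of a comparison, slide as a block, the replicate number as a block, the deposited values, detection by the per-spot flag, an estimated correlation for lists, and leaving out each array. Chosen after seeing the data were array brightness as a covariate, leaving out the dimmest arrays (caNrf2 replicate 3 and dnNrf2 replicate 2), and the median pixel signal in normexp, in place of the mean pixel signal that the plan named. Probe sequences and GC content were not analysed here. The reference annotation (GRCm38.p6) is of another build than the arrays' grid, so it was used only for names and neighbours.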

Results

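MicroRNA (miRNA) levels were measured in the skin of newborn mice at postnatal day 2.5 on 12 single-colour arrays, 1 array per RNA sample. The samples formed 4 groups of 3. One line carried a constitutively active form (caNrf2) of Nrf2, the transcription factor that switches on antioxidant and detoxification genes, and was set against K5Cre(wt) controls. The other carried a dominant-negative form (dnNrf2) and was set against wt controls. The series text calls the controls littermates, and nothing beyond sample numbers says that the samples of a group were separate animals, so p-values measure the spread between these samples. The arrays carried no probe for Nrf2 mRNA, so neither transgene could be checked.

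Of 1079 mouse miRNAs on the array, 334 were detected on all 12 arrays and 653 on none, and 387 entered the tests. The number detected per array was 366.7 ± 6.66 (SD, n = 3) in K5Cre(wt), 366.3 ± 16.7 (SD, n = 3) in caNrf2, 393.3 ± 7.64 (SD, n = 3) in wt and 388 ± 24.6 (SD, n = 3) in dnNrf2. By a two-sided exact permutation test, no difference in detection was found between caNrf2 and K5Cre(wt) (p = 1) or between dnNrf2 and wt (p = 0.8); 3 arrays against 3 allow no p below 0.1. Between the control groups, 26.67 more miRNAs were detected in wt than in K5Cre(wt), at that smallest possible exact p of 0.1. The 75th percentile of signal over the miRNAs detected everywhere ran from 1704 on caNrf2 replicate 3 and 1740 on dnNrf2 replicate 2 to 4003 on dnNrf2 replicate 1. The number of arrays limited the precision: the median standard error (SE) of a log2 change was 0.122.

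The first comparison asked which miRNAs depend on activated Nrf2 in skin. In caNrf2 skin, miR-29a was 1.46-fold higher than in K5Cre(wt) skin (95% interval 1.26 to 1.69, n = 3 per group) and miR-29b 1.54-fold higher (1.31 to 1.81); the miR-29 family is best known for repressing collagen and other matrix mRNAs. miR-672 rose 1.96-fold (1.55 to 2.49) from a low level, well above background on 2 of the 3 K5Cre(wt) arrays and all 3 caNrf2 arrays. Its log2 change was as low as 0.285 among the alternatives, and its call was lost with normexp background. miR-375, best known from pancreatic islets, was 1.43-fold lower (1.25 to 1.62). miR-138, studied mostly in neurons, rose by 1.23 on the log2 scale (SE 0.16) from a level at the edge of detection: it was well above background on no K5Cre(wt) array and on 2 of the 3 caNrf2 arrays. Under the main settings this bounds the rise at 1.37-fold or more, but the log2 change was 0.232 with normexp background and 0.163 with mean log2 probe values, both below that bound and not past the threshold.

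These 5 were the miRNAs past an adjusted p of 0.05 in limma among the 387 tested, 4 higher and 1 lower. The adjusted p was 0.00601 for miR-138, 0.0123 for miR-672, miR-29b and miR-375, and 0.0134 for miR-29a. Each of the 5 separated all 3 caNrf2 arrays from all 3 controls; 60 of the 387 miRNAs (15.5%) did so, against 10% by chance. At an unadjusted p under 0.05 there were 18, 14 higher and 4 lower, where chance gives 19.4. Named by the fixed rule without passing were miR-29c (log2 change 0.33, SE 0.12), miR-205* (0.27, SE 0.08), miR-7a (0.34, SE 0.11), miR-130b (-0.20, SE 0.06) and miR-30c-1*, which was detected in neither group.

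On slide 1 (1 array per group) miR-29a stood at 0.745, miR-29b at 0.74, miR-672 at 1.06, miR-138 at 1.36 and miR-375 at -0.473 on the log2 scale. On slide 2 (2 per group) they stood at 0.45, 0.562, 0.93, 1.16 and -0.533 in that order. The shared signs are no further evidence, since groups that do not overlap keep their sign in any subset of arrays. With slide as a block all 5 passed, with adjusted p from 0.0166 to 0.0294. Both probes of each of the 5 moved the same way, for example by 0.595 and 0.53 for miR-29a. Of the 12 arrays, the 2 probes lay above background on 0 and 2 for miR-138 and on 1 and 10 for miR-672. For these 2 miRNAs the match rests partly on signal near background. The calls were fragile: 1 miRNA passed without K5Cre(wt) replicate 3, 2 without K5Cre(wt) replicate 1, 3 without caNrf2 replicate 1, 3 without the dimmest arrays, 2 with normexp background, 2 when scaled over all miRNAs, 3 without a filter, 12 with array weights and 0 on the deposited values. Only 2 of the 5 were among the 3 without caNrf2 replicate 1, where miR-99b* was gained. Without a filter, too, 2 of the 5 remained, and miR-138-1* was gained. On log2 change alone, miR-29b ranged from 0.463 to 0.647 and miR-29a from 0.422 to 0.596 over 31 alternatives, whereas miR-138 ranged from 0.163 to 1.60 (over 30), miR-672 from 0.285 to 1.48 and miR-375 from -0.639 to -0.320. By calls kept the order was another: miR-138 passed in 26 of 30 alternatives and miR-29b, miR-375 and miR-672 in 24 of 31 each. miR-29a passed in the fewest, 21 of 31, and was lost, among others, after quantile normalization and when scaled to the median.

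**Figure D1:**
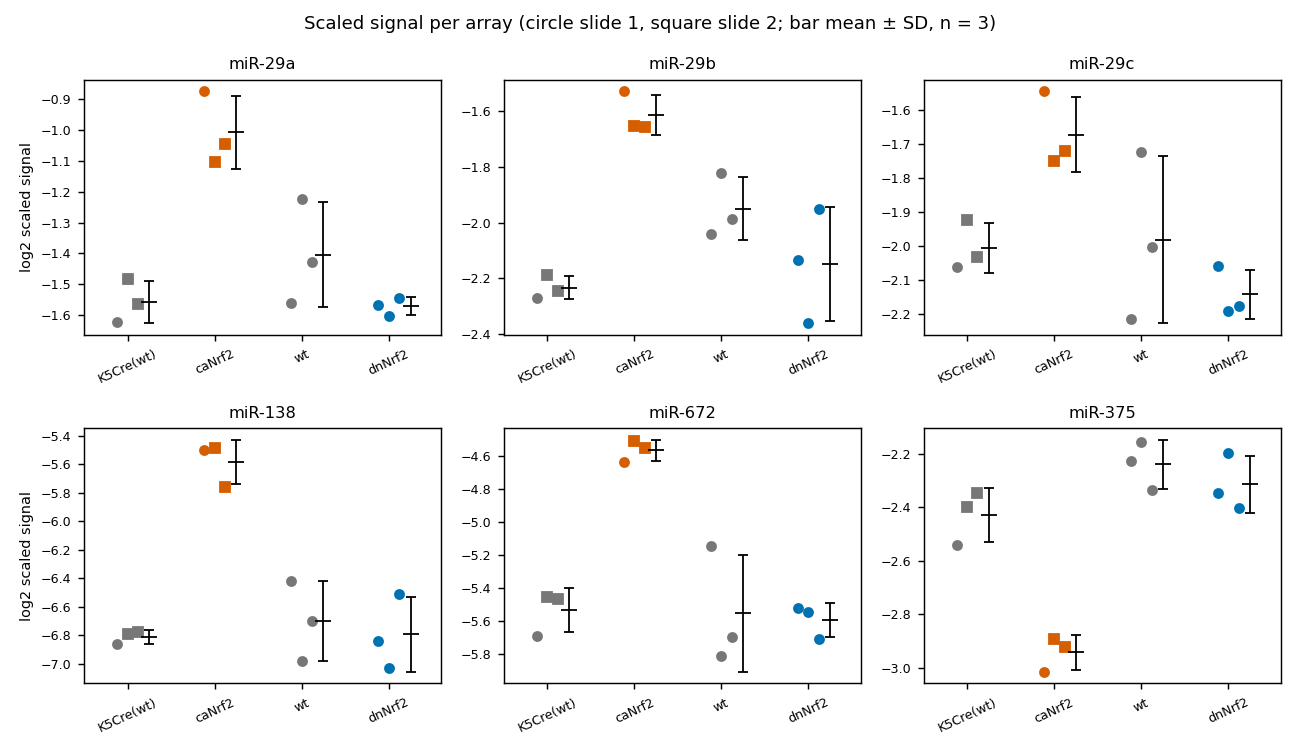
Log2 scaled signal (no unit) of miR-29a, miR-29b, miR-29c, miR-138, miR-672 and miR-375 on each array of the 4 groups; circles are slide 1, squares slide 2, bars the mean ± SD of 3 arrays. The caNrf2 arrays lie apart from the K5Cre(wt) arrays in all of these panels, including miR-29c, which did not pass the test (adjusted p = 0.634).

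Of 18 miRNA lists fixed before the data were examined, 17 had enough tested members for a list test. The miR-29 family was higher as a list in caNrf2: of its 3 tested members 2 rose, and 3 passed when adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.0599 with an estimated correlation). The family was chosen knowing the published study of these samples, so that count is not independent evidence, and its members are close in sequence, so their probes may share signal. Its median change was 0.74 within slide 1 and 0.45 within slide 2. In the reference annotation (GRCm38.p6) Mir29a lies beside Mir29b-1, and Mir29b-2 beside Mir29c.

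The miR-200 family (epithelial), which maintains the epithelial state by repressing Zeb1 and Zeb2, shifted lower as a list without any member passing alone. Its 8 tested members had a median of -0.102, 7 of them negative, with miR-200a at -0.16 (SE 0.08) and miR-200b at -0.12 (SE 0.10); the camera adjusted p was 0.00142, and adjusted p = 0.552 with an estimated correlation. The median was -0.14 within slide 1 and -0.103 within slide 2. The shift was past the threshold neither after quantile normalization (0.222), nor on the deposited values (0.106), nor without K5Cre(wt) replicate 1 (0.0738), nor by fry (adjusted p = 0.886). In dnNrf2 all 8 members were negative too (median -0.0662, camera adjusted p = 0.231). The interaction showed no difference for this list (camera adjusted p = 0.625), so the shift was not shown to be particular to caNrf2.

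The remaining lists did not pass in caNrf2. The keratinocyte and epidermal list (18 tested, median 0.0524) included miR-203 at -0.11 (SE 0.09) and miR-205 at 0.15 (SE 0.09), which limit and maintain epidermal progenitors, respectively. Medians of the other cell-type lists were 0.0262 for dermal mesenchyme and smooth muscle (17 tested), 0.0481 for skeletal muscle (6), 0.0377 for leukocyte (10), -0.0449 for erythroid (3) and 0.0381 for melanocyte and nerve (5, of which miR-138 rose; camera adjusted p = 0.638). Endothelial miR-126-3p (0.03, SE 0.08) and miR-126-5p (0.22, SE 0.10) were too few for a list test. The miR-17-92 cluster and its paralogues stood at -0.041, the miR-30 family at -0.0548, let-7 at -0.00323, the miR-15 and miR-16 family at -0.036, the miR-99 and miR-125 clusters at -0.0495, the miR-23, miR-24 and miR-27 clusters at 0.032, the proliferation and wound list at 0.0414 and the imprinted Dlk1-Dio3 locus at 0.0324. In the list of miRNAs reported to target Nrf2 or Keap1 mRNA or to depend on Nrf2 (23 tested, median 0.0302), 1 rose, miR-29b, which was put there knowing the published study. Camera adjusted p-values of these lists ran from 0.0667 to 0.837.

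The second comparison asked which miRNAs depend on Nrf2 activity normally present in skin. In dnNrf2 skin no miRNA passed an adjusted p of 0.05 against wt in limma (smallest 0.0988), with 33 at an unadjusted p under 0.05, 21 higher and 12 lower, where chance gives 19.4. The 10 with the smallest p, which did not pass, were all higher in dnNrf2. Among them miR-31, known to be induced in wounded and psoriatic epidermis, stood 1.32-fold above wt (95% interval 1.17 to 1.49, n = 3 per group). miR-211*, whose hairpin is listed next after the melanocyte gene Trpm1 in the reference annotation, stood 2.37-fold above (1.55 to 3.61). The other arm, miR-211, had a log2 change of -0.172 (SE 0.0967), and miR-721 stood 2.54-fold above (1.51 to 4.27).

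The log2 changes of the rest of these were 0.55 for miR-3077*, 0.66 for miR-3102*, 0.74 for miR-5105, 0.56 for miR-1982*, 0.67 for miR-1249, 0.84 for miR-149* and 0.53 for miR-1897-5p. miR-721 and miR-149* were well above background on 1 of the 3 wt arrays, and miR-3077* on 2 of the 3 arrays of each group. For miR-149* and miR-3077*, 1 probe lay above background on 0 arrays and showed a change of 0, so the change rests on the other probe. The groups did not overlap for 46 of the 387 miRNAs (11.9%, against 10% by chance). The 3 tested miR-29 members had negative changes and did not pass, miR-29a at -0.17 (SE 0.10), miR-29b at -0.20 (SE 0.10) and miR-29c at -0.16 (SE 0.12). All 6 arrays of this comparison lay on slide 1. Without dnNrf2 replicate 2, a dim array, 3 passed: miR-3102* (log2 change 0.44, adjusted p = 0.00808), miR-211* (0.84, 0.00808) and miR-721 (0.85, 0.0355), while miR-149* stood at 0.526 and miR-1249 at 0.445 without passing; 4 passed when scaled over all miRNAs, which shifted the median of all log2 changes to -0.198, and 3 with array brightness as a covariate.

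**Figure D2:**
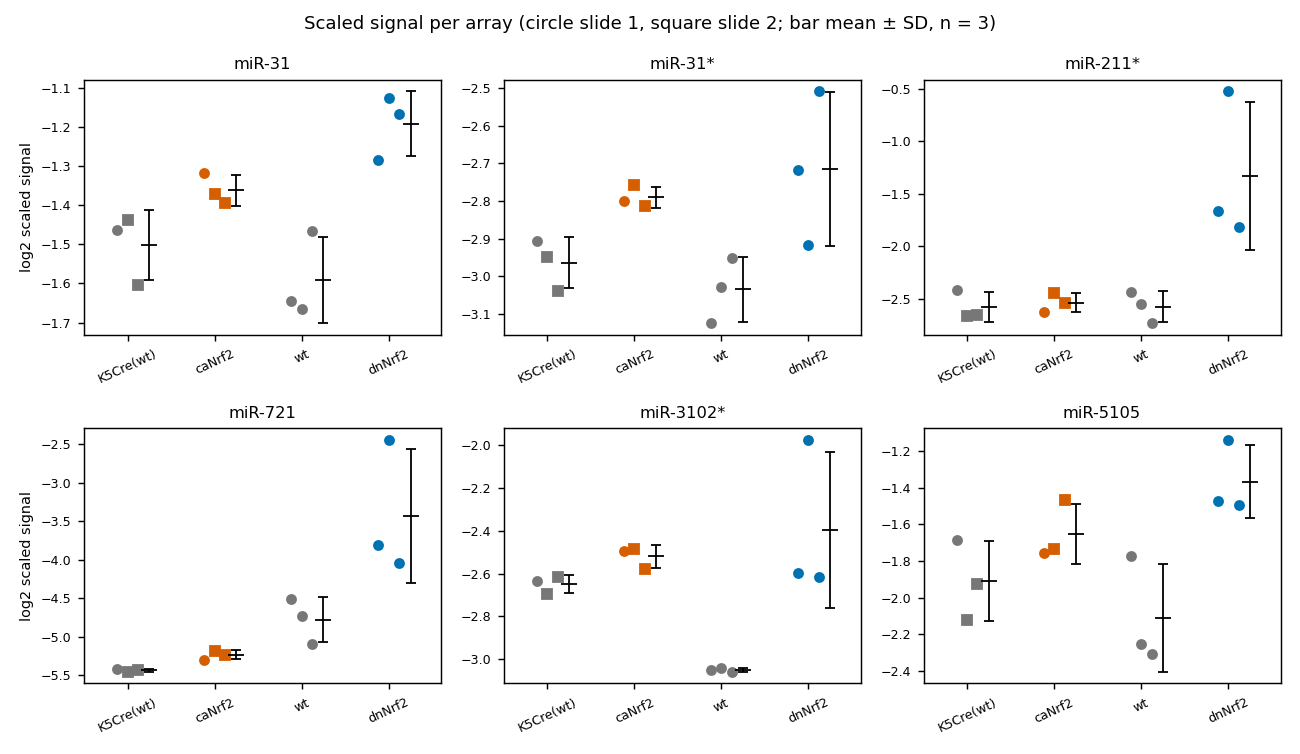
Log2 scaled signal (no unit) of miR-31, miR-31*, miR-211*, miR-721, miR-3102* and miR-5105 on each array of the 4 groups; symbols and bars are as in the plot of the caNrf2 miRNAs. The dnNrf2 arrays lie above the wt arrays in each panel, although no miRNA passed the test in this comparison (smallest adjusted p = 0.0988).

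No list passed in dnNrf2 (smallest camera adjusted p = 0.1, smallest 0.804 with an estimated correlation). When adjusted over the list alone, miR-31 was higher in the keratinocyte and epidermal list (18 tested, median -0.087). In the proliferation and wound list (12 tested, median -0.0189), miR-31 and miR-31* were higher and miR-146b, a brake on inflammatory signalling, lower when adjusted over the list alone (-0.304, SE 0.0915). In the melanocyte and nerve list (5 tested, median -0.0933), the 1 member past that adjustment was miR-211*. The dermal mesenchyme list (17 tested, 15 negative) had a median of -0.133, the miR-17-92 cluster -0.105, and the list reported to target or depend on Nrf2 -0.125, each with an adjusted p of 0.1. Medians were -0.167 for miR-29, -0.0662 for miR-200, -0.0345 for skeletal muscle, -0.0929 for leukocyte, -0.294 for erythroid, -0.0843 for let-7, -0.0466 for miR-30, -0.101 for miR-15 and miR-16, 0.0342 for miR-99 and miR-125, -0.0751 for miR-23, miR-24 and miR-27 and 0.00667 for Dlk1-Dio3. Endothelial miR-126-3p and miR-126-5p stood at -0.16 (SE 0.08) and -0.17 (SE 0.10). List calls appeared under some alternatives: 6 with normexp background, 5 without wt replicate 1, 4 without dnNrf2 replicate 3, 1 without dnNrf2 replicate 2 and 1 with mean log2 probe values.

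The third comparison tested whether the effect of caNrf2 differed from that of dnNrf2, as an interaction in the same model. It did for 3 miRNAs: miR-138 (difference in log2 change 1.32), miR-29b (0.82) and miR-29a (0.71), each with an adjusted p of 0.0421. miR-138 was well above background on no array outside caNrf2, so its difference has no exact size; with mean log2 probe values it was 0.163 and did not pass. miR-672 (1.01, adjusted p = 0.0666) did not pass. At an unadjusted p under 0.05 there were 24, where chance gives 19.4. The calls ended with slide as a block (adjusted p = 0.0867 for all 3, at the same differences), without the dimmest arrays, with normexp background, with Agilent's total gene signal and on the deposited values. Without a filter all 3 were lost as well, and the 1 call there was miR-138-1*. Both miR-29a and miR-29b were lost when scaled to the median or over all miRNAs. Scaling over all miRNAs still gave 3 calls, with miR-30c-1* and miR-672 in their place. Quantile normalization gave 3 too, with miR-29a lost and miR-672 gained. They also ended, to a count of 0, without any 1 of K5Cre(wt) replicates 1, 2 or 3, caNrf2 replicates 1, 2 or 3, wt replicate 3 and dnNrf2 replicates 1 or 2; 1 remained without wt replicate 2.

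Across the 387 miRNAs the log2 changes of caNrf2 and dnNrf2 correlated with Pearson's r of 0.40 and Spearman's rho of 0.47, and 64.3% had the same sign. The comparisons share no arrays, and miRNAs are not independent replicates; a jackknife over arrays gave r a standard error of 0.367, so r was not distinguishable from 0, and it fell to 0.0999 without caNrf2 replicate 3. 1 miRNA had an unadjusted p under 0.05 in both comparisons, with opposite signs, where independent lists give 1.53.

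**Figure D3:**
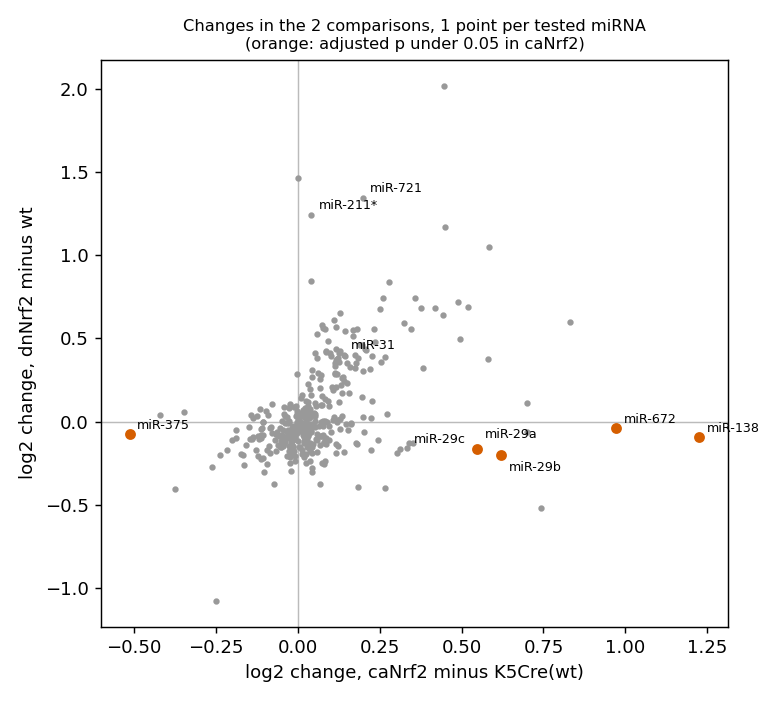
Log2 change of each of the 387 tested miRNAs in caNrf2 against K5Cre(wt) (horizontal) and dnNrf2 against wt (vertical), with the 5 that passed in caNrf2 in orange. The orange points lie near or below 0 on the vertical axis, and the correlation over all points is 0.40.

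The control groups were compared to give the scale of differences between lines. Of the 387 miRNAs, 10 differed between wt and K5Cre(wt), 7 higher in wt and 3 lower, with 75 at an unadjusted p under 0.05 where chance gives 19.4. miR-146a, a brake on inflammatory signalling, was 1.39-fold higher in wt (95% interval 1.22 to 1.58, n = 3 per group), miR-186 1.54-fold (1.29 to 1.84), and miR-200a 1.30-fold (1.14 to 1.48). miR-15b was 1.36-fold lower (1.18 to 1.56), miR-425 1.29-fold (1.15 to 1.45) and miR-335-5p 1.30-fold (1.14 to 1.49). Under the main settings miR-5121 was at least 1.55-fold and miR-5099 at least 1.06-fold higher, both well above background on no K5Cre(wt) array, and miR-30c-1* was well above background on no array of either group. miR-148a* passed too, but it was well above background on no K5Cre(wt) array and no bound above 1 could be given. With normexp background none of the 10 passed, the log2 changes of miR-5099 (-0.049), miR-30c-1* (-0.193) and miR-148a* (-0.187) turned negative, and those of miR-5121, miR-186 and miR-146a were 0.018, 0.039 and 0.124. The miR-15 and miR-16 list was lower in wt (8 tested, all negative, camera adjusted p = 0.0341; adjusted p = 0.502 with an estimated correlation).

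The wt arrays all lay on slide 1, with 1 of the 3 K5Cre(wt) arrays, and with slide as a block the count was 0. On slide 1 alone (3 wt arrays and 1 K5Cre(wt) array) the 10 differences kept their signs, for example 0.564 for miR-146a and -0.482 for miR-15b. These arrays are among those that gave the calls, so the kept signs are no independent evidence. The count was also 0 with normexp background, without a filter, and without any 1 of the K5Cre(wt) arrays, caNrf2 replicate 2 or wt replicate 1; it was 2 without wt replicate 2, 4 without caNrf2 replicate 1 and 23 without dnNrf2 replicate 2. Line, Cre background and slide were not separated by this comparison.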

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

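The slide test and the cell-type tests below were chosen only after their results were seen, and the brightness covariate after the array signals were seen. The cell-type test was first run without the called miRNAs, a form that argued against all cell types but leaves out what it tests, then over all lists together, which left the explanation open, then split by cell type, and last given an error over arrays as well as over list members, which reopened red blood cells.

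The effects of caNrf2 and dnNrf2 differed for miR-138 (difference in log2 change 1.32), miR-29b (0.821) and miR-29a (0.715), by an interaction test. miR-138 was well above background on no array outside caNrf2, so its difference has no exact size. Of 100 regroupings of the arrays within both comparisons, the real one included, 4 gave at least 3 miRNAs, the highest other 4; this share is under 0.05. These random regroupings did not keep slide, and with slide as a block the count was 0, so chance is not taken as excluded.

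In caNrf2, miR-138, miR-672, miR-29b and miR-29a were higher and miR-375 lower. A linear effect of array brightness is argued against, since with it as a covariate the median share of the change kept was 1.02 and all 5 passed. Mean log2 brightness differed by only -0.140 between the groups, which left the covariate little room. Slide is argued against by the design: both groups had 1 array on slide 1 and 2 on slide 2, so a slide effect equal in both cancels. Within either slide each of the 5 showed at least 0.821 of its change. A shift of the epidermal, mesenchymal, muscle or white blood cell lists as large as the 5 changes is argued against as well. The largest median change of these lists was 0.102 in size. Upper limits, which cover the error between arrays, were at most 0.277, below the smallest change of 0.513. This cannot decide on cells in which the 5 are more concentrated than the list members are. Endothelial cells, with 2 tested members, were not tested. More or fewer red blood cells (median 0.0449 in size, upper limit 0.669) and melanocytes or nerve cells (0.0381, upper limit 0.665, in a list that holds miR-138) could not be excluded; an effect of the transgene is the biological explanation the design names, and it may apply but stays untested, as does signal shared between miR-29 probes. Of the 10 splits of the 6 arrays, 1, the real one, gave 5 miRNAs and the highest other 0, and 10 splits are too few for a share under 0.05.

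Probes for 7 viral miRNAs gave signal on at least 1 array, 4 of them on all 12, among data that no comparison used, whereas the negative control probes were detected on none. mcmv-miR-M23-1-5p was the brightest, with a median signal of 148 (56.56 to 213.9). The labels mention no infection.

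The spike-in dmr_3 varied 8.42-fold between arrays, with 3471 on K5Cre(wt) replicate 2, 4145 on caNrf2 replicate 1 and 6727 on dnNrf2 replicate 2, and 13910 to 29210 on the other arrays. The spike-in dmr_6 ran from 1405 to 10260 and was lowest on the same 3 arrays, at 1405, 1478 and 2638 in that order. The spike-ins dmr_285 and dmr_31a ran from 3569 to 5565 and from 1600 to 2227. No difference in dmr_3 signal was found between caNrf2 and K5Cre(wt) by a two-sided exact permutation test (p = 1) or between dnNrf2 and wt (p = 0.5).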

How the results depend on the processing

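The brightness covariate, leaving out the dimmest arrays and the median pixel signal in normexp were chosen after seeing the data. Of 5702 alternative values of 185 named results, 248 lost the call, 25 gained one and 3 reversed. The other 5426 kept their side of the threshold, and among them 220 changed sign with neither value past it. Calls under the main settings numbered 5 in caNrf2, 0 in dnNrf2, 3 in the interaction and 10 between the controls. The 248 losses fell on these alone, and most of the 5426 had no call to lose. The cause was not tested unless stated. The floor, the trend and the median over spots left every count here within 1.5 times. The miR-29 list passed under every setting of the list test except the estimated correlation. Signal near background limits miR-138, whose log2 change was 0.232 with normexp and 0.163 with mean log2 probe values.

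miRNAs changed in caNrf2 (5, 4 higher and 1 lower) numbered 2 when scaled over all miRNAs (2 higher, 0 lower), 2 with normexp (2 higher, 0 lower), 3 without a filter (2 of the 5, and miR-138-1*), where more miRNAs were tested, 12 with array weights, 0 on deposited values and 3 without the dimmest arrays. In dnNrf2 (0) they numbered 4 when scaled over all miRNAs, 3 with the brightness covariate and 3 without the dimmest arrays. The interaction (3) gave 1 when scaled to the median, 0 with normexp, 0 with total gene signal, 1 without a filter (miR-138-1*, none of the 3), 5 with array weights, 0 with slide as a block, 0 on deposited values and 0 without the dimmest arrays. An unchanged count hid other losses: scaling over all miRNAs gave 3 without miR-29a and miR-29b, and quantile normalization gave 3 without miR-29a. The control groups (10) gave 5 when scaled over all miRNAs, 0 with normexp, 2 with total gene signal, 0 without a filter, 4 among miRNAs detected on all arrays, 28 with array weights, 0 with slide as a block, 3 on deposited values and 16 without the dimmest arrays. Lists shifted in caNrf2 (2) numbered 0 with an estimated correlation, 1 after quantile normalization, 12 without a filter, 4 with only the 6 arrays and 1 on deposited values; in dnNrf2 (0), 6 with normexp and 1 with mean log2 probe values. Against the control groups' call, miR-30c-1* reversed to -0.193, miR-148a* to -0.187 and miR-5099 to -0.049, each with normexp. Scaling moved the median dnNrf2 change by over 0.1, to -0.198 over all miRNAs and -0.237 on deposited values; the miR-29 members stayed above 0 in caNrf2 under each scaling.

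Leaving out single arrays gave 1 to 6 miRNAs in caNrf2 (1 without K5Cre(wt) replicate 3, 2 without K5Cre(wt) replicate 1, 3 without caNrf2 replicate 1), 0 to 3 in dnNrf2 (3 without dnNrf2 replicate 2), 0 to 4 in the interaction (0 without any K5Cre(wt) or caNrf2 array, wt replicate 3 or dnNrf2 replicates 1 or 2, and 1 without wt replicate 2) and 0 to 23 between the controls (0 without any K5Cre(wt) array, caNrf2 replicate 2 or wt replicate 1, 2 without wt replicate 2, 4 without caNrf2 replicate 1, 23 without dnNrf2 replicate 2). Of the 3 caNrf2 calls without caNrf2 replicate 1, 2 were among the 5 of the main settings. Without dnNrf2 replicate 3 the interaction gave 3, with miR-29a lost and miR-30c-1* gained. Lists numbered 1 to 3 in caNrf2 (1 without K5Cre(wt) replicate 1) and 0 to 5 in dnNrf2 (5 without wt replicate 1, 1 without dnNrf2 replicate 2, 4 without dnNrf2 replicate 3). The correlation of changes ran from 0.0999 (without caNrf2 replicate 3) to 0.481. The difference in miRNAs detected ran from -9.667 to 6.333 in caNrf2 and from -16.83 to 7.667 in dnNrf2.

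Replicate numbers did not pair the samples: same-numbered arrays correlated at -0.50, 0.151 and -0.0188 in the caNrf2 comparison and -0.403, -0.242 and 0.102 in the dnNrf2 comparison, and 2 of 12 arrays correlated best with their own number. With the replicate block the counts were 1 in caNrf2, 0 in dnNrf2, 0 in the interaction and 0 between the controls.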

Other observations

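The brightness covariate and the test without dnNrf2 replicate 2 on the dnNrf2 miRNAs were chosen only after the data were seen.

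Both arms of a hairpin are cut from 1 precursor, so a change in the precursor would move them together. Over 76 hairpins with both arms tested, the log2 changes of the arms correlated with r of 0.224 in caNrf2 (one-sided permutation p = 0.0211, rho 0.366) and 0.132 in dnNrf2 (p = 0.126, rho 0.236). Neither reached the 0.3 set in advance nor lay clearly below it, so a change of the precursor may or may not contribute. In dnNrf2, miR-211* and miR-211 stood at 1.24 and -0.172, neither past the threshold.

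The changes in caNrf2 and dnNrf2 correlated across miRNAs with r of 0.40, which its standard error of 0.367 does not separate from 0. The tests of its causes decided nothing, since they moved r by less than that error: r was 0.208 with array brightness as a covariate, 0.369 without the dim array dnNrf2 replicate 2 and 0.469 over miRNAs detected on all arrays. It was 0.0999 without caNrf2 replicate 3, the dimmest array. Within groups, the first component of the deviations held 50.3% of the variance and correlated with brightness at 0.96 in size. No biological explanation was tested.

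The 10 miRNAs with the smallest p in dnNrf2 were all higher. A linear effect of array brightness is argued against, since with it as a covariate the median share of the change kept was 0.908 and all 10 exceeded 2 standard errors. Mean log2 brightness differed by only -0.204 between dnNrf2 and wt, so the covariate had little room to lower that share. It does not cover an effect of 1 dim array that is not linear. The dim array dnNrf2 replicate 2 could not be excluded as a contributor, since the share was 0.722 without it. An effect of the transgene remains among the open explanations. The count of miRNAs passing was 0, and all 10 of 10 splits gave as many, the highest other 0. With a real count of 0 every split gives at least as many, so the splits could decide nothing.

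Between the control groups, 10 miRNAs passed in the real split of the 6 arrays, and the highest of the other splits gave 0; 1 of 10 splits, the real one, gave as many, which is too few splits for a share under 0.05.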
